A study of Mus musculus with 2 samples.

How the data were processed

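Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map trimethylation of lysine 27 of histone H3 (H3K27me3), the histone mark laid down by Polycomb repressive complex PRC2. The tissue was whole kidney of B6NCrl mouse embryos at embryonic day 15.5, with both sexes pooled. Per the labels, replicate 1 came from 78 embryos and replicate 2 from 62 embryos, and each biological replicate joined its own technical replicates. The pools were separate biological replicates of a single group (n = 2), so the design allowed no test between groups.

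The deposited data were peak lists in narrowPeak format on the mouse assembly mm10: 1 list per replicate, 1 list called by the authors on the pooled alignments of both replicates, and 1 list of replicated peaks that the submitters' notes derive from the other 3 lists. The authors' fold enrichment of each peak, a linear ratio, and the deposited −log10 p of each peak are the values of their peak caller, and they were used only to describe, rank or filter peaks within a list. The smallest −log10 p was close to 2 in every deposited list (2.02 in replicate 1 and 2.00 in replicate 2). The labels name a possible control experiment. The aligner, the peak caller, its settings and the rule for replicated peaks are not given in the sources used here. The submitters' notes list 1 more source file for replicate 1 than for replicate 2, and the kind of that file is not given. Read alignments were not used here, so the depth behind each list is unknown and no interval that needs depth is given. A deeper library or a looser threshold lengthens a peak list, which limits comparisons of peak numbers between lists. A caller of narrow peaks also breaks a broad mark into pieces, so covered bases and merged domains are given beside peak counts.

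Gene positions came from GENCODE M21 and sequence from GRCm38.p6, the assembly that mm10 stands for. All peak and gene ends lay within the chromosome lengths of that sequence. Only the assembled chromosomes 1 to 19, X and Y were used, and coordinates are 1-based. The transcription start site (TSS) was the 5′ end of the gene record, and 1 record was kept per symbol, which left 21911 protein-coding genes of 21938 records. A promoter was called marked when merged peaks covered 25% or more of the window from 1000 bp upstream to 1000 bp downstream of the TSS. The replicated list gave the main calls. Each replicate's own list gave the spread, printed as mean ± SD over n = 2. Promoter CpG content was the observed/expected CpG ratio within 500 bp on either side of the TSS, called CpG-rich at 0.6 or more and CpG-poor under 0.4.

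Shared peaks were those that overlapped a peak of the other replicate by 1 bp or more. Chance overlap came from 100 random placements of the peaks on their own chromosomes outside assembly gaps, made with bedtools shuffle at fixed seeds. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 35 lists at a threshold of 0.05. Effect sizes are log2 odds ratios with 0.5 added to each cell. Each list was also set against 10000 random lists matched on the decile of promoter CpG content. For these the size is the log2 ratio of the marked count to the mean count of the random lists, with 0.5 added to each. Genes are not replicates, so these p-values describe the peak lists and not the variation between embryos. Domains were made by merging replicated peaks no more than 3 kb apart, and long domains spanned 10 kb or more. Promoter, exon, intron and intergenic bases were counted in that order of priority. Only protein-coding genes were used for this, so non-coding genes outside them count as intergenic.

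The groups, tests, 35 gene lists, promoter definition, alternatives and the rule for named genes were fixed before the data were examined. The lists covered kidney lineages (nephron progenitor, ureteric bud, early nephron, mature tubule, podocyte and stroma), cell types that could be present in the organ (endothelial, immune and erythroid), neighbouring organs (gonad and adrenal), regulators of other lineages (neural, muscle and heart, endoderm, skin and bone), pluripotency and germline genes, housekeeping genes, Polycomb components, imprinted genes, cell cycle inhibitors and 16 gene families. Named genes were a fixed set of sentinel genes; up to 4 marked members of each list with the most covered promoters and up to 2 members without a peak in any list; genes with a TSS in the 10 longest domains; and up to 10 marked genes outside all lists, ranked by coverage in both replicates and then by fold. Other genes named beside them to spell out a count were chosen after their values were seen. Alternatives covered the overlap rule, the promoter window and its minimum coverage, transcript starts, −log10 p minimums of 5 and 10, the pooled list, the intersection of the replicates, each replicate alone, CpG limits, merging distances and N bases.

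Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and with bedtools 2.31.1. The scripts were tested on simulated data. Promoter calling recovered 100% of 200 planted promoters. Each planted peak was centred on its TSS and well above the coverage limit, so this checked the code and not the sensitivity. No peaks were planted away from these promoters, so false calls were not tested. In the simulation of shared peaks, 50% were planted and 50% were found among 4000 peaks. In 100 simulated runs of the gene list tests over 21911 genes, 93.2% of lists planted at 60% marked and 0.900% of lists at the base rate passed the adjusted threshold.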

Results

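H3K27me3 peaks were mapped in embryonic day 15.5 mouse kidney, a stage at which nephron progenitors, the branching ureteric bud, early nephrons, stroma and vessels are present together. Replicate 1 (78 embryos) gave 110393 peaks and replicate 2 (62 embryos) gave 94499 peaks, a mean of 102446 ± 11239 (SD, n = 2). Peaks covered 53.5 Mb in replicate 1 and 49.2 Mb in replicate 2, or 1.88% ± 0.112 of the assembled chromosomes (SD, n = 2). The pooled list held 129436 peaks over 69.4 Mb, and the replicated list held 65196 peaks over 53.3 Mb. The median peak was 286 bp long in replicate 1, 297 bp in replicate 2 and 469 bp in the replicated list. The authors' fold enrichment had a median of 2.79 and a maximum of 17.6 among replicated peaks. Depth is unknown, and neither replicate had a peak on chromosome Y.

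The first comparison asked how far the replicates marked the same places. In replicate 1, 50.6% of peaks (55827) overlapped a peak of replicate 2, against 4.15% ± 0.0596 (SD) over 100 random placements. In replicate 2, 58.4% of peaks (55171) overlapped a peak of replicate 1, against 4.80% ± 0.0586. Broad and strong peaks recurred most. Of peaks of 1 kb or more, 99.6% of 7619 in replicate 1 and 99.8% of 7648 in replicate 2 were shared, whereas 46.9% and 54.7% of shorter peaks were. Peaks with a −log10 p of 10 or more were shared in 98.6% of cases for replicate 1 and 99.1% for replicate 2. The Jaccard index of covered bases was 0.438. All replicated peaks had the coordinates of a pooled peak, and 70.1% of them (45687) touched peaks in both replicates' own lists while 2.43% touched neither. With reciprocal overlap of 50% the shared portion was 26.2% for replicate 1 and 30.6% for replicate 2.

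Promoters held far more of the mark than their length would give. Replicated peaks placed 9.78% of their bases in promoters, which make up 1.52% of the assembled chromosomes, a ratio of 6.45. Exons held 6.94% of peak bases against 3.17% of the chromosomes, introns 35.4% against 34.1%, and intergenic sequence 47.9% against 61.2%. The replicates' own lists placed 9.43% ± 0.303 of bases in promoters and 48.4% ± 0.404 in intergenic sequence (SD, n = 2). With a promoter reaching 2500 bp on either side of the TSS, promoters held 22.6% of peak bases.

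Of 21911 protein-coding genes, 3369 (15.4%) had a marked promoter, and 1033 promoters were covered from end to end. The replicates' own lists marked 3270 and 3116 promoters, a mean of 3193 ± 109 (SD, n = 2), and 2872 were marked in both. Across genes, the covered percent of the promoter in the replicates had a Pearson r of 0.966 and a Spearman rho of 0.868, with genes not being independent replicates. Of 35 gene lists, 24 were marked more often than other genes, 4 less often, and 7 did not pass the test. All 28 lists that passed also passed in the same direction with either replicate's peaks alone.

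**Figure D1:**
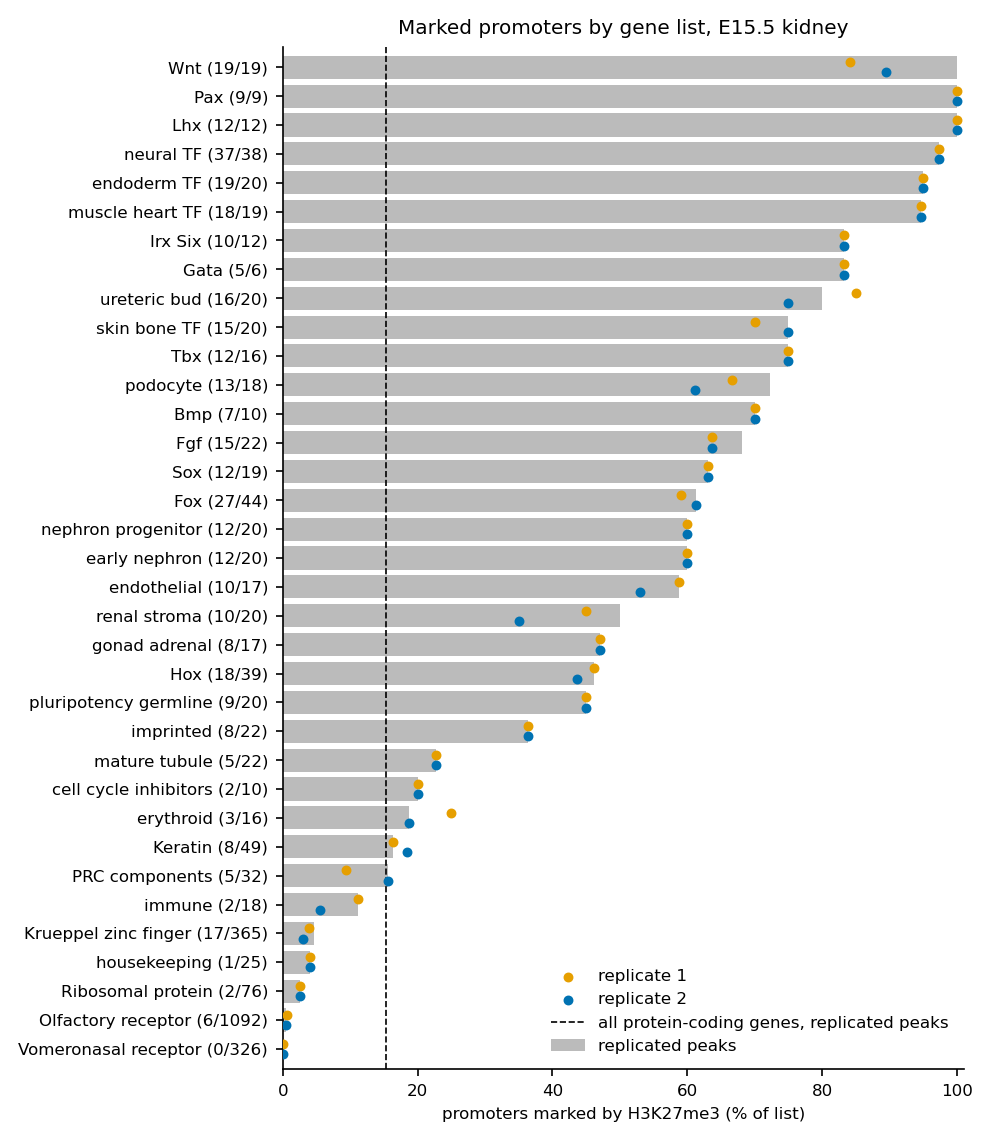
Percent of promoters marked by H3K27me3 in each of 35 gene lists, with bars for the replicated list, points for each replicate's own peaks and a dashed line at the 15.4% of all protein-coding genes. Marked and total genes stand beside each name, and lists of regulators of other lineages lie near the top.

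Transcription factors that specify other organs were marked almost throughout. Among neural regulators 37 of 38 were marked (log2 odds ratio 7.12, Benjamini-Hochberg adjusted Fisher's exact p = 3.92e-28), including Ascl1 and Atoh1, proneural factors, and Barhl1 and Barhl2, all covered from end to end in both replicates. The bHLH factors Neurog2 and Olig2 of neurons and oligodendrocytes were fully covered too, with folds of 8.70 and 12.2 at their strongest replicated peak. Muscle and heart regulators were marked at 18 of 19 genes (6.09, adjusted exact p = 2.10e-13), among them the myogenic factor Myod1 (chromosome 7, TSS 46376474) and the heart factors Hand1, Hand2 and Gata5. Endoderm regulators were marked at 19 of 20 genes (6.17, adjusted exact p = 4.07e-14), among them the pancreatic factor Pdx1 (chromosome 5, TSS 147269959), the intestinal factor Cdx2 (chromosome 5, TSS 147307270), Barx1, Foxa1 and Foxa2. Skin and bone regulators were marked at 15 of 20 genes (3.96, adjusted exact p = 1.41e-08), with Alx3, Barx2, Dlx4 and Msx1 fully covered. Genes without a peak in any list included Neurod4 among neural genes, Isx among endoderm genes, and Foxn1 and Trp63, factors of epithelial development, among skin genes.

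The lists of kidney lineages, except mature tubule, were also marked more often than other genes. In the ureteric bud list, the epithelium that forms the collecting system, 16 of 20 promoters were marked (4.34, adjusted exact p = 8.62e-10). Ret, the receptor that drives bud branching (chromosome 6, TSS 118197718), and Wnt9b, the bud signal that induces nephrons, were fully covered in both replicates. Wnt7b was covered at 96.4% ± 5.13, Emx2 at 96.0% ± 1.80, Gata3 at 91.6% ± 7.28 and Hnf1b at 88.9% ± 0.460 (SD, n = 2). Etv5, a target of Ret signalling, and Spry1, which restrains it, had no peak. Aqp2, the water channel of the collecting duct, was unmarked in the replicated list, with 42.6% covered in replicate 1, 0% in replicate 2 and 28.6% in the pooled list. Nephron progenitor genes were marked at 12 of 20 promoters (3.02, adjusted exact p = 1.12e-05). Six2, the regulator that keeps progenitors self-renewing (chromosome 17, gene 85684277 to 85688274, TSS 85688274), was fully covered in both replicates, as were Six1 and Uncx, and Pax2 was covered at 96.0% ± 0.566. Wt1, needed by progenitors and podocytes, was covered at 53.5% ± 18.8 and Osr1, an early marker of the kidney field, at 29.5% ± 3.39. Replicated peaks covered 92.95% of the Wt1 promoter and 59.2% of the Osr1 promoter. Fgf20 and Ncam1 had no peak.

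Early nephron genes were marked at 12 of 20 promoters (3.02, adjusted exact p = 1.12e-05). Lhx1, required for the renal vesicle (chromosome 11, TSS 84525535), was covered at 93.9% ± 8.66 (SD, n = 2), and Fgf8, the Notch target Hes5, Irx1 and Irx2 were fully covered in both replicates. Hnf4a and Hnf1a, regulators of the proximal tubule, had no peak, nor did Ehf. Podocyte genes were marked at 13 of 18 promoters (3.76, adjusted exact p = 2.62e-07). Nphs1 (chromosome 7, TSS 30458315) and Nphs2, which encode the slit diaphragm proteins nephrin and podocin, were fully covered in both replicates, as was Lmx1b, and Podxl was covered at 93.2% ± 3.18. The podocyte and stromal factor Tcf21 was covered at 50.4% by replicated peaks but 36.6% and 10.6% in the replicates' own lists. Cdkn1c and Dach1 had no peak. Among replicated peaks with a −log10 p of 10 or more the podocyte list no longer passed (1.71, adjusted exact p = 0.0543; 4.08e-09 to 0.0543 over 15 settings). Stromal genes were marked at 10 of 20 promoters (2.46, adjusted exact p = 0.000462), with Foxd1, the factor of stromal progenitors, at 83.2% ± 9.83, Pdgfra at 86.8% ± 3.75, Penk at 97.6% ± 3.43 and Smoc2 fully covered. Col3a1 and Dcn, matrix genes of fibroblasts, had no peak. The stromal list also lost its call at a −log10 p of 10 or more (1.51, adjusted exact p = 0.0788; 0.000214 to 0.0788 over 15 settings).

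Mature tubule genes, most of them transporters, were marked at 5 of 22 promoters and did not pass the test (0.79, adjusted exact p = 0.430). The marked members were the sodium channel subunits Scnn1b (98.3% ± 2.40) and Scnn1g (83.2% ± 13.6), the endocytic receptor Lrp2 (74.3% ± 5.05), the water channel Aqp3 (65.6% ± 7.21) and Calb1 (49.95% ± 7.78; SD, n = 2). Umod, the main urinary protein, Aqp1 and Atp6v1g3 had no peak. Of this list 3 genes had a CpG-rich promoter, and all 3 were marked, which passed the test against CpG-rich promoters (5.02, adjusted exact p = 0.00812; 0.00812 to 0.811 over 15 settings).

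Among lists of other cell types in the organ, endothelial genes were marked at 10 of 17 promoters (2.95, adjusted exact p = 8.31e-05). The vascular factors Sox17 (chromosome 1, TSS 4497354) and Sox18, the tight junction gene Cldn5 and the VEGF receptor gene Flt1 were fully covered in both replicates, whereas the adhesion gene Cdh5 and Egfl7 had no peak. Genes of the neighbouring gonad and adrenal were marked at 8 of 17 promoters (2.30, adjusted exact p = 0.00264), with Dhh, Dmrt1, Foxl2 and Gata4 fully covered and the steroid enzyme genes Cyp11a1 and Cyp11b1 without a peak. Of further cell types, immune genes (2 of 18, −0.26, adjusted exact p = 1.00) and erythroid genes (3 of 16, 0.51, adjusted exact p = 0.794) did not pass the test. The marked immune genes were C1qc and Fcgr1 (24.8% in replicate 2's own list, just below the limit), and the marked erythroid genes were Tal1 (96.5% ± 0.389; SD, n = 2), Klf1 and Hba-x. Adgre1, Aif1, Gata1 and Epb42 had no peak.

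Pluripotency and germline genes were marked at 9 of 20 promoters (2.19, adjusted exact p = 0.00213), with Sox2, Tfap2c and Utf1 fully covered in both replicates and Dazl and Ddx4 without a peak. Among CpG-rich promoters, 4 of 9 of these genes were marked and the list did not pass (1.93, adjusted exact p = 0.0723; 0.000296 to 0.0723 over 15 settings). Imprinted genes were marked at 8 of 22 promoters (1.69, adjusted exact p = 0.0164), including Rasgrf1, Kcnq1, Phlda2 and Dlk1, with no peak at Cdkn1c and Igf2r. That list did not stand apart from random lists of the same CpG content (adjusted permutation p = 0.109). It also did not pass among CpG-rich promoters (0.63, adjusted exact p = 0.710) or with 1 bp covered (1.25, adjusted exact p = 0.0742), and its adjusted p ran from 0.00254 to 0.710 over 15 settings in exact or permutation tests. Of cell cycle inhibitors, the neighbouring genes Cdkn2a (chromosome 4, TSS 89294653) and Cdkn2b were fully covered in both replicates and the other 8 genes were unmarked, Cdkn1b among them (0.69, adjusted exact p = 0.743). With any annotated transcript start, the inhibitor list passed as marked more often (2.28, adjusted exact p = 0.0209; 0.0209 to 0.903 over 15 settings). Polycomb components were marked at 5 of 32 promoters (0.14, adjusted exact p = 1.00). Those were Pcgf5 (90.5% ± 13.5; SD, n = 2), Pcgf1, Cbx2, Cbx4 and Cbx8. Cbx2 was below the limit in both replicates' own lists (21.6% and 10.6%) and Cbx4 in replicate 1's (22.6%), whereas the methyltransferase gene Ezh2 (chromosome 6, TSS 47595341), Aebp2 and Bmi1 had no peak. Of 25 housekeeping genes, 1 was marked, the X-linked glycolytic gene Pgk1 (33.2% ± 6.93), and Actb and Atp5b had no peak (−1.57, adjusted exact p = 0.196). On autosomes alone, a setting chosen after seeing the data, housekeeping genes passed as marked less often (−3.06, adjusted exact p = 0.0469; 0.0469 to 0.386 over 15 settings).

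Families of developmental regulators and secreted signals carried the mark widely. The 19 Wnt ligand genes (7.75, adjusted exact p = 2.97e-15), the 9 Pax genes (6.71, adjusted exact p = 1.28e-07) and the 12 Lhx, Isl and Lmx1 genes (7.11, adjusted exact p = 6.68e-10) were marked without exception in the replicated list. In the replicates' own lists 16 and 17 Wnt genes were marked. Genes of the Irx family and of the family of Six1 and Six2 were marked at 10 of 12 promoters (4.53, adjusted exact p = 7.81e-07), Gata genes at 5 of 6 (4.34, adjusted exact p = 0.000654) and Tbx genes at 12 of 16 (3.94, adjusted exact p = 3.97e-07). The exceptions included Six5, Gata1, Tbx6 and Tbx10. Sox genes were marked at 12 of 19 promoters (3.202, adjusted exact p = 6.14e-06) and Fox genes at 27 of 44 (3.12, adjusted exact p = 2.33e-11), with Sox1, Sox14, Foxb1 and Foxb2 fully covered and Sox11, Sox12, Foxj2 and Foxj3 without a peak. Fgf genes were marked at 15 of 22 promoters (3.51, adjusted exact p = 1.04e-07) and Bmp genes at 7 of 10 (3.56, adjusted exact p = 0.000251).

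The 4 lists marked less often than other genes were olfactory receptors, vomeronasal receptors, zinc fingers and ribosomal proteins. Olfactory receptor genes were marked at 6 of 1092 promoters (−5.01, adjusted exact p = 3.65e-69) and vomeronasal receptor genes at 0 of 326 (−6.92, adjusted exact p = 2.56e-23). Zinc finger genes of the Zfp series were marked at 17 of 365 promoters (−1.88, adjusted exact p = 4.58e-10), Zfp853 and Zfp296 among them. Ribosomal protein genes were marked at 2 of 76 promoters, Rpl3 and the X-linked Rps4x (−2.44, adjusted exact p = 0.000883). Keratin genes were marked at 8 of 49 promoters and did not pass the test (0.17, adjusted exact p = 0.894), although Krt8 and Krt18, the keratins of simple epithelia, were marked in both replicates. No olfactory receptor gene had a CpG-rich promoter and a single vomeronasal receptor gene did, so among CpG-rich promoters only the zinc finger and ribosomal lists were marked less often.

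The next comparison set regulators used in the kidney against regulators of other lineages. Of 43 kidney transcription factors 28 (65.1%) were marked, and of 97 factors of other lineages 89 (91.8%) were, a log2 odds ratio of −2.52 (two-sided Fisher's exact p = 0.000282). The difference was present in replicate 1 (60.5% against 90.7%, exact p = 7.48e-05) and in replicate 2 (60.5% against 91.8%, exact p = 2.34e-05). Kidney factors were also covered over a smaller part of the promoter, with a median of 69.2% against 100% and 13 of 43 fully covered against 72 of 97. The 15 unmarked kidney factors were Etv5, Eya1, Hnf1a, Hnf4a, Hnf4g, Hoxa11, Mafb, Mecom, Meis1, Meis2, Nr2f1, Nr2f2, Pbx1, Six4 and Sox9. Eya1 was above the limit in the pooled list alone (33.0%). Meis1, Meis2 and Pbx1 are cofactors of Hox proteins, Nr2f1 and Nr2f2 are nuclear receptors of mesenchyme, and Hnf1a, Hnf4a and Hnf4g act in proximal tubules. The 28 marked kidney factors included Six2, Pax2, Lhx1, Gata3 and Irx1, so the lists differed in degree. Genes of both lists were chosen from general knowledge of the lineages, and bulk tissue gives no value per cell type.

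**Figure D2:**
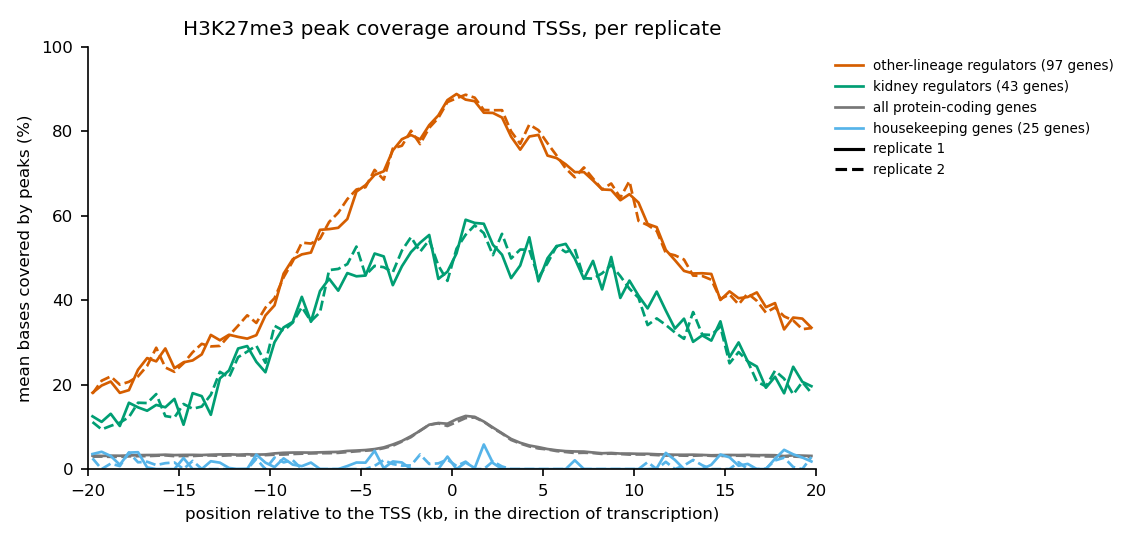
Mean percent of bases covered by peaks in 500 bp bins from the TSS, in kb, for kidney regulators, regulators of other lineages, housekeeping genes and all protein-coding genes, with solid lines for replicate 1 and dashed lines for replicate 2. Regulators of other lineages lie above kidney regulators, and both lie above all genes.

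Promoter CpG content went with the mark, but not in a straight line. CpG-rich promoters were marked at 1786 of 10065 genes (17.7%) and CpG-poor promoters at 634 of 8773 (7.23%), a log2 odds ratio of 1.47 (Fisher's exact p = 4.42e-107). The highest level lay between these classes: promoters with an observed/expected ratio from 0.4 to 0.6 were marked at 949 of 3073 genes (30.9%). That exceeded the CpG-rich class (log2 odds ratio 1.05, Fisher's exact p = 3.93e-52), a comparison chosen after the values were seen. Above it the marked percent fell to 11.1% at ratios of 0.9 or more.

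**Figure D3:**
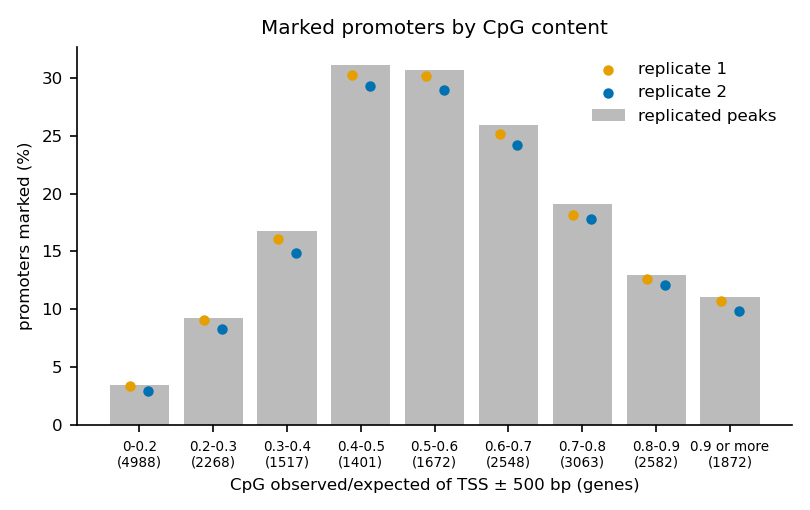
Percent of promoters marked by class of CpG observed/expected ratio within 500 bp of the TSS, with bars for the replicated list, points for each replicate and gene numbers under each class. The bars rise to 31.1% in the class from 0.4 to 0.5 and fall to 11.1% in the last class.

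The 4 Hox clusters, whose genes pattern the body axis, were covered unequally. HoxC (chromosome 15, 102921103 to 103036852) was covered at 79.9% by replicated peaks and at 71.2% ± 0.0800 in the replicates, and all 9 of its genes were marked. HoxD (chromosome 2, 74668310 to 74765142) was covered at 33.0% (replicates 28.9% ± 1.48), HoxA (chromosome 6, 52155590 to 52260880) at 19.9% (18.3% ± 1.02) and HoxB (chromosome 11, 96194316 to 96368256) at 18.3% (17.3% ± 0.0289; SD, n = 2). Outside HoxC, marked promoters lay toward the ends of the clusters. Hoxa1, Hoxb1 and Hoxd1 at the anterior end and Hoxa13, Hoxb13 and Hoxd13 at the posterior end were marked in both replicates, as were Hoxa10, Hoxd11 and Hoxd12. None of the 19 genes of paralog groups 2 to 9 in HoxA, HoxB and HoxD was marked, Hoxa4 and Hoxa6 among them, whereas all 5 such genes of HoxC were. Not all of these promoters were separate, since some gene records are long and start near another gene. The windows of Hoxc5 (TSS 102967443) and Hoxc10 (TSS 102966796) overlapped and had the same strongest peak. Hoxd3 and Hoxd4 had almost the same TSS (74711927 and 74711929), and the TSS of Hoxa3 (52213336) lay past Hoxa6. Hoxa11, which acts in metanephric development, was unmarked in the replicated list and in both replicates (13.3% ± 5.37 covered; SD, n = 2), but 40.6% of its promoter was covered in the pooled list, above the limit. Over all 39 Hox genes 18 were marked (2.25, adjusted exact p = 1.02e-05). In replicate 2's own list Hoxc6 fell below the limit, at 20.3% covered. The grouping by paralog was chosen after the values were seen.

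**Figure D4:**
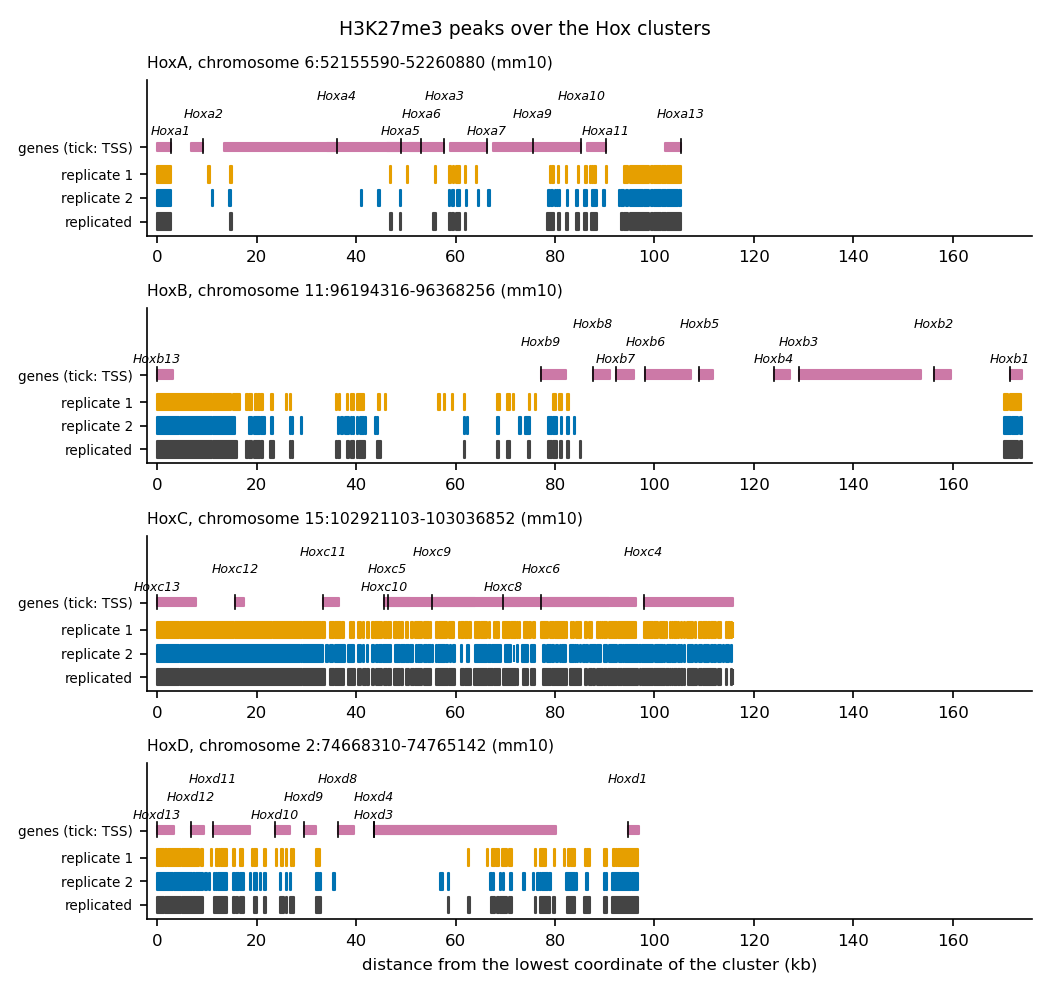
Peaks of replicate 1, replicate 2 and the replicated list over the HoxA, HoxB, HoxC and HoxD clusters in kb from the lowest mm10 coordinate, with gene bodies and TSS ticks above. Peaks cover most of HoxC, and the other clusters have blocks at both ends with scattered peaks between them.

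Replicated peaks joined into 19504 domains, of which 2057 spanned 10 kb or more and held 55.03% of peak bases. Their median span was 16.3 kb, and 117 spanned 50 kb or more. The longest autosomal domain lay on chromosome 4 from 154317493 to 154609236 (292 kb) and held the TSS of B230104I21Rik. Others were on chromosome 2 from 165069816 to 165269032 with the cadherin gene Cdh22 and 1700025C18Rik, on chromosome 8 from 120814933 to 121004181 with no protein-coding TSS, and on chromosome 15 from 102893150 to 103042893 with the 9 Hoxc genes. Just past the 3 kb merging distance, the chromosome 4 domain was followed by one from 154613112 with the TSSs of Prdm16 and Actrt2. The chromosome 8 domain without a TSS was likewise followed by one from 121008696 with the TSS of Foxf1. The genes named for a domain therefore depend on where merging stopped. The neural factor gene Sox1 lay in a domain of 140.0 kb on chromosome 8. The ammonium transporter gene Rhcg lay in one of 135.1 kb on chromosome 7. The longest of all was on chromosome X from 99333528 to 99633471 (299.9 kb) and held the TSS of Pja1, whose own promoter was unmarked in the replicated list (12.5% covered) but reached 27.8% in replicate 2. Further X domains among the 10 longest held the TSSs of Smc1a, Iqsec2, Hsd17b10 and Ribc1, or that of Tsc22d3. Another, from 166992778 to 167188625, held no protein-coding TSS. The number of long domains depended on the merging distance (1036 at 1 kb) and on the list (3233 in the pooled list).

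The 10 genes outside every list with the strongest fully covered promoters were the deiodinase gene Dio3 (chromosome 12, TSS 110279068, fold 15.9), the potassium channel genes Kcnc1 (fold 14.8) and Kcnk9 (14.8), the corepressor gene Skor2 (13.6), Prmt8 (12.7), Gpr26 (12.5), the adrenergic receptor gene Adra2c (12.3), the matrix gene Bcan (12.2), the homeobox gene Hmx1 (12.2) and the morphogen gene Shh (12.1). Each was covered from end to end in both replicates.

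Chromosome X carried more peak bases than any autosome. It held 16095 replicated peaks (24.7%), and 5.29% of its bases were covered against 1.80% of autosomal bases, a ratio of 2.94. The ratio was 2.68 in replicate 1 and 2.64 in replicate 2 (2.66 ± 0.0268; SD, n = 2). X promoters were marked at 248 of 948 genes (26.2%) and autosomal promoters at 15.02% of genes (log2 odds ratio 1.00, Fisher's exact p = 6.25e-18). Among CpG-rich promoters the values were 39.8% on X and 17.2% on autosomes (1.68, Fisher's exact p = 3.46e-17). Of 40 X-linked housekeeping genes listed as subject to X inactivation 11 were marked, among them Pgk1, Ogt and Prps2. Among 10 X genes listed as escaping inactivation 2 were marked, Mid1 and Usp9x. Of 23 autosomal housekeeping genes 0 were marked. X held 534 of the 2057 long domains, and peaks filled 46.6% of their span against 70.6% for autosomal domains. The excess was absent among the strongest peaks: at a −log10 p of 10 or more, a minimum chosen for X after the lists had been read, the ratio was 0.912 for replicated peaks, 0.462 in replicate 1 and 0.325 in replicate 2. At a −log10 p of 5 or more it was 2.73, 2.15 and 1.72 in the same order.

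**Figure D5:**
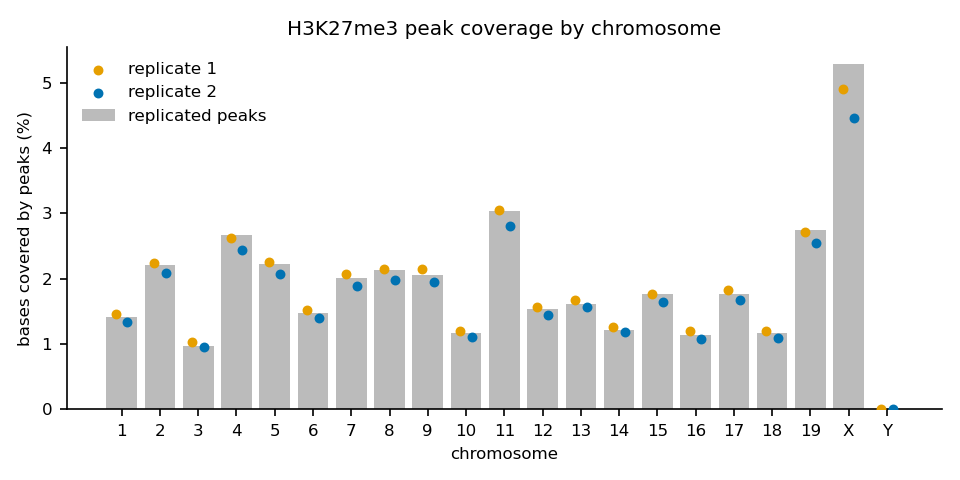
Percent of each chromosome's bases covered by H3K27me3 peaks, with bars for the replicated list and points for each replicate. Chromosome X reaches 5.29% with replicated peaks, above all autosomes, and chromosome Y has no peak.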

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

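Settings that used autosomes only, left out chromosome Y, took CpG-rich promoters for the regulator contrast, or applied a −log10 p of 10 to chromosome X were chosen after seeing the data. Marked promoter counts stayed within 1.5 times the main value in all settings run, and the contrast of kidney with other-lineage regulators (log2 odds ratio from −4.29 to −2.26, Fisher's exact p from 5.22e-07 to 0.00226 over 13 settings) and the CpG-rich contrast kept their direction and passed throughout. Lists marked more often numbered 22 to 25; lists marked less often fell to 2 among CpG-rich promoters. Shared peaks of replicate 1 and replicate 2 moved to 39.9% and 46.5% with 50% of the peak covered and to 26.2% and 30.6% with reciprocal overlap, and replicate 1 reached 62.0% with the top 20000 peaks. Coverage was 1.71% at a −log10 p of 5, 2.55% in the pooled list and 1.81% to 1.96% with either replicate alone. The promoter portion of peak bases was 10.7%, 8.22% and 9.21% to 9.64% in the same order, and 22.6% with the wider promoter, which by construction takes in more sequence. Long domains numbered 3233 in the pooled list and 1036 with merging within 1 kb. At a −log10 p of 5, in the pooled list and with either replicate alone, HoxA coverage was 16.7%, 22.2% and 17.6% to 19.05%, HoxB 16.7%, 21.4% and 17.2% to 17.3%, HoxC 77.9%, 83.4% and 71.2% to 71.3%, and HoxD 30.8%, 38.5% and 27.8% to 29.9%. The X to autosome ratio was 2.73, 3.05 and 2.64 to 2.68 in that order, 3.00 without N bases, and 0.912 at a −log10 p of 10, which turned its direction. Lists that changed sign were not past the threshold in either setting, except the vomeronasal list, whose log2 value became 0.63 where a single CpG-rich member remained. Polycomb components gave −0.013 with 1 bp covered, −1.47 with 50% covered, −1.04 in the 500 bp window, −0.031 in the pooled list, −0.18 in the intersection, −0.13 against CpG-matched lists and −0.57 to 0.27 with either replicate alone. Erythroid genes gave −0.45 with 50% covered, −0.12 in the 2500 bp window, −0.37 at a −log10 p of 10 and −0.48 in the intersection. Immune genes gave 0.33 with 1 bp covered, 0.14 in the pooled list and 0.36 against CpG-matched lists, and keratins gave −0.092 with 50% covered, −0.73 at a −log10 p of 10 and −0.049 against CpG-matched lists. Values against CpG-matched lists are log2 ratios of marked to expected counts and the others are log2 odds ratios, so their sizes are not comparable. The cause of these changes was not tested where the setting itself does not show it. Unknown depth limits any comparison of peak numbers between lists.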

Other observations

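The grouping of genes by symbol stem, the tests of Hox CpG content and of bulk tissue, and the reading of X at a −log10 p of 5 in each replicate were chosen after the results were seen. Of 356 symbol stems with at least 8 genes, 43 were marked more often than other genes and 15 less often at an adjusted threshold of 0.05 (Fisher's exact tests, Benjamini-Hochberg). The stems Wnt (19 of 19) and Nkx had the smallest p among those marked more often. The synaptotagmin genes (Syt), calcium sensors of vesicle release, were marked at 14 of 17 promoters (log2 odds ratio 4.52, adjusted exact p = 1.02e-07; 12 in replicate 1 and 14 in replicate 2). All 8 metabotropic glutamate receptor genes (Grm) were marked in both replicates (6.55, adjusted exact p = 9.20e-06). Serotonin receptor genes (Htr) were marked at 10 of 14 promoters, and the potassium channel stems Kcna and Kcnh at 7 of 8 each. Voltage-gated calcium channel genes (Cacna) and potassium channel genes of the Kcnk stem were each marked at 9 of 14. Homeobox genes of the Nkx stem were marked at 14 of 14 promoters. Collagen genes (Col) were marked at 24 of 45 promoters (2.66, adjusted exact p = 1.97e-07) and solute carriers (Slc) at 91 of 371 (0.86, adjusted exact p = 9.53e-05). The Slc genes of the mature tubule list were all unmarked.

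The 15 stems marked less often included histone genes (Hist, 0 of 67 promoters; −4.62, adjusted exact p = 0.000393), the Eif stem, mainly translation initiation factors (0 of 55; −4.34, adjusted exact p = 0.00291), the Rpl stem of ribosomal proteins (1 of 54; −2.70, adjusted exact p = 0.0183) and mitochondrial ribosomal proteins of the large subunit (Mrpl, 0 of 49; −4.17, adjusted exact p = 0.00576), where 1 Mrpl gene was marked in replicate 1. The stems Mrps (0 of 29, adjusted exact p = 0.0899), Eef (1 of 13, adjusted exact p = 0.859) and Rps (3 of 44, adjusted exact p = 0.396) did not pass. Stems group genes by symbol alone, and of the 3 marked Rps genes only Rps4x encodes a ribosomal protein, the others being the kinase genes Rps6ka3 and Rps6kl1. Further stems at 0 included vesicle sorting genes (Vps, 0 of 35), beta-defensins (Defb, 0 of 42), taste receptors (Tas, 0 of 38) and the X-linked Rhox homeobox genes (0 of 34).

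Kidney regulators were marked less often than regulators of other lineages. The values argue against promoter CpG content as the main cause. Among CpG-rich promoters 20 of 29 kidney factors and 63 of 64 other factors were marked, a log2 odds ratio of −4.29 (Fisher's exact p = 8.18e-05). The factors were not matched on CpG content within that class, so a smaller contribution is not excluded. At a −log10 p of 10 or more the counts were 22 of 43 and 88 of 97 (−3.15, Fisher's exact p = 5.22e-07). The difference therefore did not rest on weak peaks at the factors of other lineages. A stricter minimum cannot show whether weak signal at kidney factors fell below the calling threshold, and that possibility was not tested. That 65.1% of kidney factors were marked at all may reflect bulk tissue with several cell types, in which a gene used by few cells stays marked in the rest. Separate cell types would be needed to decide, so this explanation stays open.

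The HoxC cluster was covered more than HoxA, HoxB and HoxD. The values argue against CpG content of the promoters as the main explanation. Genome-wide marked rates by CpG class give 22.7% marked in HoxC and 21.1% in the other clusters. That is in the observed direction but far from the 100% and 30% seen. The median promoter CpG ratio of HoxC (0.651) also lay between those of HoxB (0.472) and of HoxA (0.691) and HoxD (0.720). The rates are only an assumed profile for Hox genes, so a small contribution is not excluded. A candidate biological explanation, that HoxC genes are silent in more of the kidney's cells than genes of the other clusters, was not tested, since expression was not analysed here.

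Chromosome X was covered above autosomes in both replicates. If weak peaks near the calling threshold were the cause, neither replicate should show an X excess at a −log10 p of 10 or more. That prediction was met, with ratios of 0.462 in replicate 1 and 0.325 in replicate 2. At 5 or more the ratio was still 2.15 and 1.72 in the same order, so the explanation by weak peaks stays open. The median fold was 2.80 for X peaks and 2.68 for autosomal peaks in replicate 1, and 2.85 for both in replicate 2. The inactive X of the female embryos in the pool and a uniform error in the X copy number of the control cannot be told apart here. The test meant to separate them compared gene-body coverage between 10 X genes listed as escaping inactivation and 40 X housekeeping genes listed as inactivated. Inactivation of these genes was not measured in these embryos. The test was void because both medians were 0 with replicated peaks and in replicate 2 (permutation p = 1). In replicate 1 the medians were 0 and 0.623% (permutation p = 0.415). A mark on the inactive X, present in a minority of X copies of a mixed-sex pool, might also give weak peaks, so the low scores do not exclude it.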
